A study of Danio rerio with 29 samples.

How the data were processed

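RNA from pools of 5 whole larvae was sequenced as stranded poly(A) libraries with 75 bp reads over 4 lanes. Larvae were raised at 28.5 C under 14 h light and 10 h dark and treated from 3 days post fertilization with 8 µM enoxolone or with vehicle, 0.1% DMSO and 50 ppm Tween-20 in embryo medium. The authors estimated abundance with Salmon (version not given) against genome build GRCz11 and named DESeq2 1.42; annotation release, trimming and read filters are not stated. One of the deposited tables holds expected counts, estimated reads per gene without normalization or length scaling, and the other deposited table holds TPM, length-scaled relative abundance by the authors, in which every library sums to the same total. Both cover 32520 genes and the same 29 libraries, with lanes merged and replicates kept apart. For 11661 genes the table gives the identifier in place of a name, and 8382 of these were named from a reference table, which held 89.8% of all identifiers.

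Groups follow the labels: treatment, hours of treatment and replicate number, where a replicate number is 1 clutch. The analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Expected counts were rounded, genes were filtered with filterByExpr at its minimum count of 10, and libraries were scaled by TMM. Enoxolone was compared with vehicle within each duration by edgeR's quasi-likelihood test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design treats each duration as an experiment of its own, and the labels do not state that clutch was a model term. The test therefore had no clutch term. The labels pair the arms by clutch, and the pairing was visible in the counts: residual correlations between arms of the same clutch were 0.215 to 0.467, while the highest between different clutches was 0.0997. These residuals are deviations from group means and cancel within a group. Low values between clutches thus follow in part from high ones within clutches and are no separate sign of pairing. Because of the pairing, the value with clutch as a block is given wherever it changes a call or moves a count by more than 1.5 times. A fit of all 29 libraries gave the average effect and the test of treatment by duration, and vehicle at 24 h was compared with vehicle at 4 h.

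The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule allowed the 8 largest rises and falls per duration among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 called members per list, a panel of 26 genes of which 25 were matched, the 10 smallest p for the average effect and for the difference between durations, and the 5 largest rises and falls in vehicle. The text names part of the genes this rule allows. The 46 gene lists matched 1323 members, with 80 not matched. Lists were tested with camera on log-CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, and again with an estimated correlation. camera called 17, 10, 20, 26 and 21 lists at 4, 8, 12, 16 and 24 h with the preset correlation, and with the estimated correlation it called 0 in each comparison, the lowest adjusted p being 0.0945. The text gives part of these lists.

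The procedure was tested on simulated data. At the size of the 12 h comparison edgeR recovered 83% of genes changed 2-fold and 97% of genes changed 4-fold, with 6.25% of calls false, and at the size of the 24 h comparison 64% and 90%, with 14.4% false. With no gene changed at the 24 h size, edgeR called 1 gene without the block and 51 with it. The simulated libraries held no clutch effect. These rates therefore do not show how either test behaves on libraries paired by clutch. A simulated 1.5-fold rise of the cholesterol synthesis list passed with an estimated correlation at both sizes (camera adjusted p = 0.00231 and 0.0425). Simulated genes were drawn independently of each other, so this does not show how that test performs on correlated genes.

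Alternatives were DESeq2's size factors or upper-quartile scaling in place of TMM, the DESeq2 test, no filter or a filter at 1 CPM, clutch as a block, the sequencing series as a covariate, each clutch left out, limma on log2 TPM with a pseudocount of 1 or 0.1, all 29 libraries in 1 fit, and removal of a trend on gene length. The sequencing series is not stated in the labels and was inferred from the library numbering. Omission of the library labelled vehicle 8 h, replicate 3, and of all 8 h libraries was chosen after seeing the data. No sample column was left out.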

Results

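The series holds RNA-seq counts from pools of 5 whole zebrafish larvae. The larvae carried the LipoGlo reporter, in which luciferase is fused to an endogenous apolipoprotein B gene (apobb.1), and they lived on their yolk throughout. From 3 days post fertilization they were kept in 8 µM enoxolone, a plant-derived triterpenoid known as an inhibitor of 11β-hydroxysteroid dehydrogenase, or in vehicle alone. Pools were collected after 4, 8, 12, 16 and 24 h from 3 independent clutches, one collection occasion per clutch. Each group has 3 libraries, 1 per clutch, except enoxolone at 24 h, which has 2 (clutches 1 and 2); a pool of clutch 3 at that duration was not analysed here. The 29 libraries held 19013653 to 34952955 counts each, so that a level of 1 CPM, in counts scaled to library size, stands for 19 to 35 counts. Levels are given as CPM, mean ± SD over the n libraries of a group. Differences are log2 fold changes of enoxolone over vehicle with an approximate standard error. That error is the absolute log2 fold change divided by the square root of edgeR's F statistic. Gene identifiers belong to the GRCz11 annotation and the count table gives no coordinates.

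One library stood apart from its group. In the library labelled vehicle 8 h, replicate 3, fkbp5, a co-chaperone and target of the glucocorticoid receptor, stood at 141 CPM against 4.3 and 5.24 CPM in the other vehicle pools of 8 h. pck1, which encodes a gluconeogenic enzyme, stood at 147 CPM there against 8.88 and 16.1 CPM, and the clock repressor gene nr1d1, chosen after its values were seen, at 80.7 CPM against 2.15 and 3.67 CPM. Its counts differed from those of the other vehicle 8 h pools with a chi-square per degree of freedom of 63.2 and 49.7, while the other pairs of replicates gave at most 30.2. Its label was kept in every comparison. The totals of called genes over all genes that rest on it are also given without it, while list counts include it.

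The comparison at 4 h asks which transcripts respond first to enoxolone. The called gene that rose belongs to sterol regulation. insig1, whose product holds the sterol sensor complex in the endoplasmic reticulum, stood at 33 ± 3.7 CPM (n = 3) in vehicle and 78.4 ± 8.3 CPM (n = 3) in enoxolone, a log2 fold change of 1.25 ± 0.11 (edgeR adjusted p = 0.0432). The locus si:ch211-157c3.4 fell from 41.9 ± 2.02 to 21.7 ± 1.55 CPM (log2 fold change -0.95 ± 0.08, edgeR adjusted p = 0.0432). These were the only 2 of 22499 genes past the threshold in the test without a clutch term; with clutch as a block 231 genes rose and 103 fell. Both calls ended with the filter at 1 CPM (adjusted p = 0.0535 each), with limma on log TPM (0.064 to 0.134) and without any 1 clutch (0.098 to 0.443). The call of si:ch211-157c3.4 also ended with the series covariate (0.057) and that of insig1 with all 29 libraries in the fit (0.13). With all 29 libraries and the block insig1 passed again (0.0168).

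Of 29 measured genes of the cholesterol synthesis list, 1 passed over all genes and 22 passed adjusted over the list alone, all higher; with clutch as a block 23 rose over all genes. camera gave this list an adjusted p of 1.15e-39, and adjusted p = 0.118 with an estimated correlation. hmgcra, the rate-limiting reductase of the pathway, stood at 24.8 ± 6.45 CPM in vehicle and 54.5 ± 12.6 CPM in enoxolone (log2 fold change 1.13 ± 0.22), with an edgeR adjusted p of 0.266 and, with clutch as a block, 0.00084. sqlea, which encodes squalene epoxidase, gave 1.08 ± 0.15 with adjusted p of 0.0891 and, blocked, 0.00084. The sterol-regulatory transcription factor srebf2 gave 0.75 ± 0.09 with 0.0593 and, blocked, 0.000315. In the glucocorticoid response list 0 of 27 genes passed over all genes in edgeR (7 rose with the block) and 11 were higher adjusted over the list alone (camera adjusted p 6.47e-09; adjusted p = 0.175 with an estimated correlation). Its member fkbp5 was at 3.83 ± 0.881 CPM in vehicle and 24.3 ± 9.78 CPM in enoxolone, log2 fold change 2.67 ± 0.33, with an edgeR adjusted p of 0.0593 and, blocked, 0.00024. With all 29 libraries in the fit and the block, the adjusted p at 4 h was 0.493 for fkbp5, 0.115 for hmgcra and 0.0875 for sqlea, and 0.0316 for srebf2. The apolipoprotein B gene apobb.1 stood at 1200 ± 169 and 1030 ± 176 CPM, with adjusted p of 1 and, blocked, 0.501. Leaving out any 1 clutch left no more than 1 call, and DESeq2 called 115 genes. Upper-quartile scaling called 2 higher and 1 lower gene.

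The comparison at 8 h has the doubted library among its 3 vehicle pools. Without the library labelled vehicle 8 h, replicate 3, edgeR called 24 higher and 5 lower genes, and 352 higher and 336 lower genes with clutch as a block. With it, 0 of 22200 genes passed in edgeR, with or without the block, while 928 genes had an unadjusted p under 0.05 and DESeq2 called 53 genes. Vehicle pools gave 51.6 ± 34.2 CPM (n = 3) for insig1 and enoxolone pools 98.5 ± 9.06 CPM (n = 3), a log2 fold change of 0.92 ± 0.41 (edgeR adjusted p = 1). The doubted library held 91.1 CPM of insig1, against 31.5 CPM in vehicle replicate 2 and a similar level in vehicle replicate 1. Without the doubted library insig1 was still higher in enoxolone and passed the threshold, with or without the block. fkbp5 stood at 50.1 ± 78.5 CPM in vehicle and 36.4 ± 23.3 CPM in enoxolone. Its log2 fold change of -0.48 ± 1.25 became 2.95 without the library labelled vehicle 8 h, replicate 3 (edgeR adjusted p = 0.106) and 2.6 with the block as well (adjusted p = 0.0114). The gluconeogenic gene pck1 went from -0.09 ± 0.91 to 2.15 (adjusted p = 0.0531) and, with the block, 1.98 (adjusted p = 0.000488). Of the cholesterol synthesis list, 5 of 29 genes were higher adjusted over the list alone and 0 over all genes (camera adjusted p 2.91e-18; adjusted p = 0.598 with an estimated correlation). With the block 18 were higher over the list alone.

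At 12 h the response was broad: 389 genes rose and 293 fell of 22487 tested. gck, which encodes the liver's glucose-phosphorylating kinase, fell from 22.1 ± 6.45 to 0.632 ± 0.267 CPM (n = 3 each; log2 fold change -5.09 ± 0.33, edgeR adjusted p = 0.000525), while pck1 rose from 10.8 ± 1.64 to 80.3 ± 16.5 CPM (2.89 ± 0.18, adjusted p = 0.000361). The mitochondrial uncoupling protein gene ucp3 rose by 3.07 ± 0.27, the ammonium transporter gene rhcga by 5.14 ± 0.22 and the small GTPase gene arf4b by 5.02 ± 0.47. The bile acid enzyme gene cyp8b1.1, a sterol 12-alpha-hydroxylase, fell from 24.7 ± 7.21 to 9.7 ± 1.05 CPM and the iridophore purine gene pnp4a from 38.7 ± 9.1 to 11.7 ± 1.52 CPM.

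Of the glucocorticoid response list, 11 of 27 genes rose over all genes and 15 adjusted over the list alone (camera adjusted p 2.52e-14; adjusted p = 0.124 with an estimated correlation). fkbp5 rose from 2.99 ± 0.243 to 48.3 ± 9.24 CPM (log2 fold change 4.01 ± 0.16, edgeR adjusted p = 5.6e-05), the hormone-induced transcription factor gene klf9 by 3.35 ± 0.24 and tsc22d3, which encodes the leucine zipper protein GILZ, by 0.71 ± 0.11. In cholesterol synthesis 20 of 29 genes rose, and adjusted over the list alone 24 rose and 1 fell (camera adjusted p 2e-26; adjusted p = 0.124 with an estimated correlation). insig1 reached 103 ± 4.89 CPM from 32.4 ± 5.39 CPM, and the lanosterol synthase gene lss rose by 1.14 ± 0.09. Cell cycle genes went down: 23 of 36 fell over all genes and 36 adjusted over the list alone (camera adjusted p 8.24e-33; adjusted p = 0.124 with an estimated correlation). Among them the replication clamp gene pcna fell from 267 ± 15.3 to 159 ± 8.6 CPM and the replicative helicase gene mcm6 from 75.5 ± 3.84 to 43.1 ± 4.06 CPM.

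Stress lists moved at the same duration. In the amino acid stress list 11 of 28 genes rose (18 with clutch as a block) and 21 did so adjusted over the list alone (camera adjusted p 7.12e-16; adjusted p = 0.124 with an estimated correlation). The glutathione-degrading enzyme gene chac1 was at 199 ± 16.6 and 357 ± 23.5 CPM. In the endoplasmic reticulum stress list 9 of 34 rose (16 with the block) and 18 over the list alone (camera adjusted p 8.65e-17; adjusted p = 0.262 with an estimated correlation). ddit3, which encodes the transcription factor CHOP, rose by 1.11 ± 0.11. In the hypoxia list 5 of 18 rose (8 with the block) and 6 adjusted over the list alone (camera adjusted p 7.02e-05; adjusted p = 0.124 with an estimated correlation). The glycolysis regulator gene pfkfb3 rose by 1.46 ± 0.12. In the acute phase and inflammation list 7 of 35 rose and 11 over the list alone (camera adjusted p 2.16e-05; adjusted p = 0.32 with an estimated correlation). The ubiquitin-like interferon-response gene isg15 rose by 3.96 ± 0.28 and the neutrophil chemokine gene cxcl18b by 2.42 ± 0.21. Proteasome subunit genes gave 0 of 43 calls over all genes in edgeR (15 fell with the block) and 25 lower genes adjusted over the list alone (camera adjusted p 9.59e-15; adjusted p = 0.292 with an estimated correlation). With clutch as a block 935 genes rose and 938 fell in all. Without clutch 1, 2 or 3 the calls numbered 243, 76 and 82.

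The comparison at 16 h gave 975 higher and 811 lower genes of 22613 in edgeR, and 2504 and 2209 with clutch as a block. Genes of glucocorticoid response were among those that rose. fkbp5 stood at 34.2 ± 17.8 CPM in vehicle and 239 ± 54.2 CPM in enoxolone (n = 3 each; log2 fold change 2.81 ± 0.34, edgeR adjusted p = 0.0041). pdk2b, which encodes a kinase that restrains pyruvate dehydrogenase, rose from 31.5 ± 12 to 250 ± 84.2 CPM, and cyp24a1, the vitamin D 24-hydroxylase gene, from 5.24 ± 3 to 51.9 ± 5.21 CPM. gck fell to 0.763 ± 0.122 CPM from 20.4 ± 7.68 CPM, and the D-amino-acid oxidase gene dao.1 to 0.485 ± 0.317 from 7.32 ± 4.04 CPM.

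In the glucocorticoid response list 16 of 27 genes rose; adjusted over the list alone 21 rose and 1 fell (camera adjusted p 1.85e-12; adjusted p = 0.241 with an estimated correlation). Among them were igfbp1a, which encodes an insulin-like growth factor binding protein, at 2.28 ± 0.2, the tyrosine aminotransferase gene tat at 1.97 ± 0.21, and hsd11b2, which encodes the enzyme that inactivates cortisol, from 20.4 ± 3.69 to 50.6 ± 5.94 CPM. In the cell cycle list 33 of 36 genes fell, and all 36 adjusted over the list alone (camera adjusted p 4.84e-33; adjusted p = 0.241 with an estimated correlation). The level of pcna was 224 ± 16.5 and 97.4 ± 5.9 CPM. In cholesterol synthesis 19 of 29 rose and 1 fell, or 24 and 1 over the list alone (camera adjusted p 5.4e-16; adjusted p = 0.241 with an estimated correlation). The level of insig1 was 42.9 ± 3.73 and 145 ± 8.63 CPM. In the amino acid stress list 16 of 28 rose, and adjusted over the list alone 23 rose and 1 fell (camera adjusted p 1.85e-12; adjusted p = 0.241 with an estimated correlation). In the list of p53 targets 6 of 19 rose and 1 fell (10 and 1 with the block), or 9 and 1 adjusted over the list alone (camera adjusted p 6.64e-05; adjusted p = 0.517 with an estimated correlation). pmaip1, a pro-apoptotic gene, rose by 1.67 ± 0.15.

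Called genes linked to lipoproteins went both ways at 16 h, more of them down. Of 23 measured members of the lipoprotein assembly list, 1 rose and 2 fell over all genes (3 and 10 with clutch as a block), and 1 rose and 3 fell adjusted over the list alone (camera adjusted p 0.03; adjusted p = 0.767 with an estimated correlation). The apolipoprotein gene apoa4a fell from 9.48 ± 2.38 to 1.41 ± 0.276 CPM (-2.73 ± 0.24, edgeR adjusted p = 0.00214). apobb.2, another apolipoprotein B gene, fell from 21.5 ± 7.66 to 8.33 ± 1.35 CPM (-1.35 ± 0.26, adjusted p = 0.018). angptl3, which encodes an inhibitor of lipoprotein lipase, rose by 0.7 ± 0.13. apobb.1 itself stood at 1200 ± 67 and 829 ± 314 CPM, a log2 fold change of -0.52 ± 0.23 with an edgeR adjusted p of 0.209 and, blocked, 0.0117. mttp, which encodes the transfer protein that loads lipid onto apolipoprotein B, was at 50.8 ± 11.1 and 60.8 ± 12.8 CPM (0.27 ± 0.19, adjusted p = 0.454, blocked 0.0454 and, with all 29 libraries in the fit and the block, 0.344). Without clutch 1, 2 or 3 the calls at 16 h numbered 483, 650 and 200. Upper-quartile scaling gave 809 higher and 1055 lower genes.

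At 24 h, with 2 enoxolone and 3 vehicle libraries, 1169 genes rose and 617 fell of 22858 in edgeR (3055 and 2335 with clutch as a block). Heat shock genes were among the largest rises. hsp70l, an inducible chaperone gene, stood at 15.8 ± 2.2 CPM (n = 3) in vehicle and 1100 ± 903 CPM (n = 2) in enoxolone, a log2 fold change of 6.16 ± 0.54 (edgeR adjusted p = 0.00242); its near-identical relatives hsp70.1, hsp70.2 and hsp70.3 rose by 5.73, 5.55 and 5.45, and how the reads were shared among these copies was not examined. The AP-1 transcription factor gene fosl1a rose from 2.08 ± 0.307 to 144 ± 73.7 CPM and the matrix metalloproteinase gene mmp9 from 7.14 ± 0.302 to 267 ± 187 CPM. gck fell from 11.8 ± 3.15 to 0.993 ± 0.191 CPM and the water channel gene aqp8b from 4.91 ± 0.689 to 0.478 ± 0.372 CPM.

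Of the acute phase and inflammation list 24 of 37 genes rose at 24 h, 29 adjusted over the list alone (camera adjusted p 2.37e-20; adjusted p = 0.449 with an estimated correlation). cxcl18b was at 1.41 ± 0.147 and 24.5 ± 5.48 CPM. In the heat shock list 11 of 25 rose, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p 4.61e-07; adjusted p = 0.628 with an estimated correlation). In the amino acid stress list 20 of 28 rose and 22 over the list alone (camera adjusted p 2.74e-18; adjusted p = 0.449 with an estimated correlation). sesn2, which encodes a leucine sensor of the TOR pathway, went from 7.4 ± 0.615 to 48.4 ± 5 CPM. Endoplasmic reticulum stress genes rose in 17 of 34 cases and 23 over the list alone (camera adjusted p 1.27e-14; adjusted p = 0.449 with an estimated correlation). xbp1, a transcription factor gene of the unfolded protein response, rose from 181 ± 13.7 to 386 ± 19.7 CPM. NRF2 targets, the oxidative stress list, rose in 11 of 26 cases (17 with the block, and 17 adjusted over the list alone; camera adjusted p 2.65e-10; adjusted p = 0.449 with an estimated correlation). The autophagy adaptor gene sqstm1 was at 49.7 ± 4.5 and 202 ± 21.3 CPM. In the hypoxia list 12 of 21 rose, or 13 with 1 lower over the list alone (camera adjusted p 4.93e-08; adjusted p = 0.449 with an estimated correlation). In the list of p53 targets 10 of 19 rose and 1 fell (15 and 2 with the block), or 15 and 2 adjusted over the list alone (camera adjusted p 5.97e-07; adjusted p = 0.449 with an estimated correlation).

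Proliferation genes stayed low at 24 h: 32 of 36 cell cycle genes fell, 36 adjusted over the list alone (camera adjusted p 1.35e-26; adjusted p = 0.449 with an estimated correlation). The proliferation marker gene mki67 was at 192 ± 23.2 and 72.8 ± 2.49 CPM. In the glucocorticoid response list 11 of 27 rose (20 rose and 1 fell with the block), and adjusted over the list alone 16 rose and 1 fell (camera adjusted p 5.78e-08; adjusted p = 0.551 with an estimated correlation). fkbp5 stood at 46.6 ± 31.6 and 171 ± 50.7 CPM, with an edgeR adjusted p of 0.111 and, blocked, 0.00775. In cholesterol synthesis 10 of 29 rose (18 rose and 1 fell with the block), and 17 rose adjusted over the list alone (camera adjusted p 5.97e-09; adjusted p = 0.449 with an estimated correlation). apobb.2 fell by 1.16 on the log2 scale, the triglyceride synthesis gene dgat2 from 14.9 ± 2.93 to 7.07 ± 0.324 CPM and the fetuin gene fetub from 258 ± 104 to 66.3 ± 8.47 CPM. apobb.1 was at 1080 ± 91.6 and 950 ± 16 CPM (edgeR adjusted p = 0.426). Without clutch 1, 2 or 3 the calls numbered 1596, 35 and 1308. The fits without clutch 1 or 2 hold 1 enoxolone library, taken to vary as the vehicle libraries do, and the mean log2 levels on the TPM scale were lower in enoxolone, with a median of -0.151 over all genes. Upper-quartile scaling gave 959 higher and 786 lower genes.

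**Figure D1:**
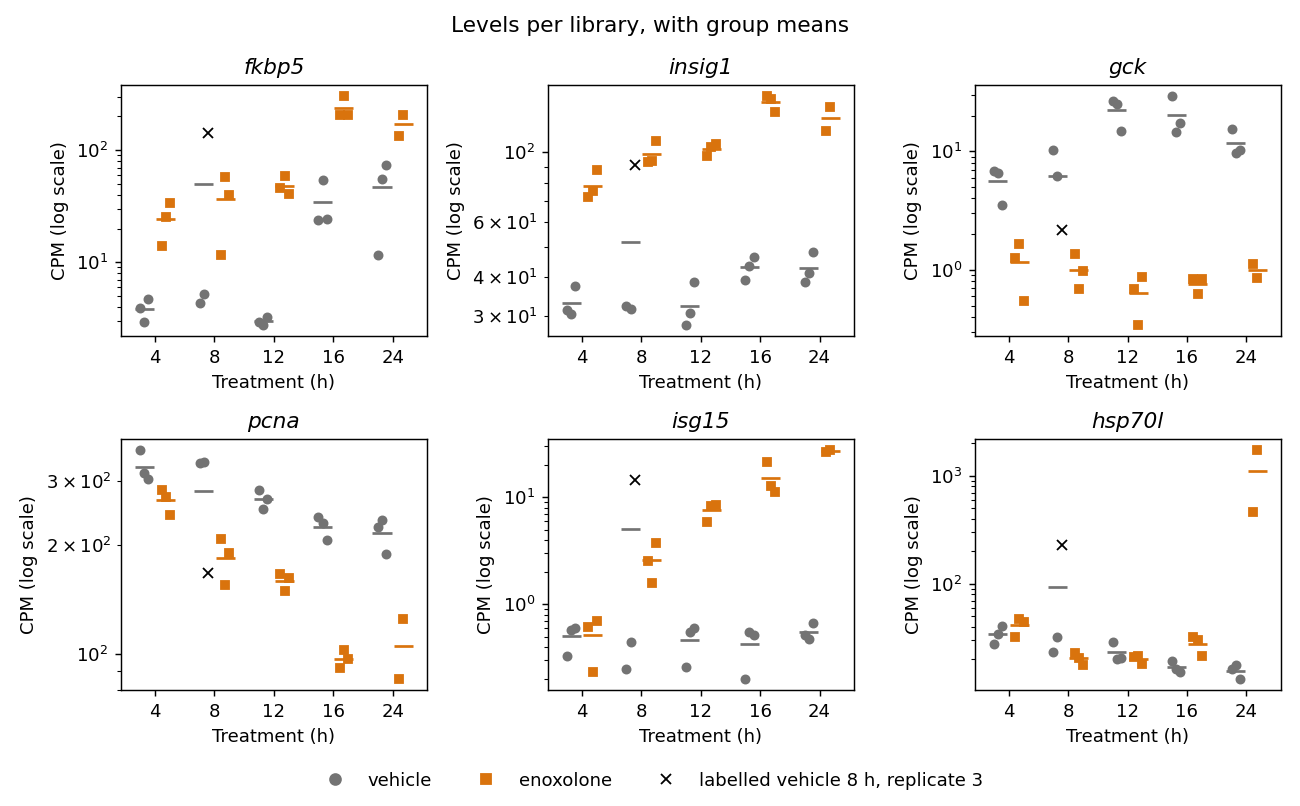
Levels of 6 genes in each of the 29 libraries (CPM, log axis) against hours of treatment; grey circles are vehicle pools, orange squares enoxolone pools, horizontal bars group means, and the cross marks the library labelled vehicle 8 h, replicate 3. That library lies at 141 CPM for fkbp5, within the range of the enoxolone pools of 16 and 24 h (135 to 302 CPM), and the enoxolone pools of 12 h lie near 0.632 CPM for gck.

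The calls of separate durations share no libraries but come from the same clutches, and their overlap was counted. Effects of clutch or sequencing series can recur at each duration. The counts for independent lists below are therefore a reference and no test. Of 388 genes that rose at 12 h and 963 that rose at 16 h among the 22229 tested at both, 322 were shared, where independent lists would share 16.8. Of 293 and 810 genes that fell, 233 were shared against 10.7. Between 16 and 24 h the shared genes numbered 541 higher (49.9 for independent lists) and 366 lower (22.2).

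Averaged over the 5 durations in a fit of all 29 libraries, 2580 genes were higher and 2861 lower of 23857 in edgeR. Sterol and acetyl-CoA genes stood among the 10 genes with the smallest p: aclya, the ATP citrate lyase gene, gave a log2 fold change of 0.63 ± 0.04, the farnesyl diphosphate synthase gene fdps 0.59 ± 0.04, the mevalonate decarboxylase gene mvda 1.01 ± 0.07 and the sterol reductase gene tm7sf2 0.93 ± 0.07. pnp4a fell by 1.34 on the log2 scale and gck by 3.65, while cyp26a1, which encodes a retinoic acid-degrading enzyme, rose by 1.05 ± 0.07. In the cell cycle list 36 of 36 genes fell, the same number adjusted over the list alone (camera adjusted p 1.86e-29; adjusted p = 0.206 with an estimated correlation). In cholesterol synthesis 24 of 29 rose and 1 fell, or 25 and 1 adjusted over the list alone (camera adjusted p 5.91e-24; adjusted p = 0.0945 with an estimated correlation). The apolipoprotein B gene apobb.1 gave -0.12 ± 0.09 (edgeR adjusted p = 0.367). Without the library labelled vehicle 8 h, replicate 3 the calls numbered 7138, and without clutch 1, 2 or 3 they numbered 2900, 1927 and 5438.

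The test of the treatment by duration interaction asks whether the effect itself differed between durations; 908 of 23857 genes passed in edgeR, and 2596 with clutch as a block. timp2b, which encodes a metalloproteinase inhibitor, gave the smallest p (edgeR adjusted p = 1.07e-05), with its effect furthest from that of 4 h by 3.18 on the log2 scale. For hsp70l (5.88, adjusted p = 0.000237), the polyamine synthesis gene odc1 (2.34, adjusted p = 0.000337) and the tyrosyl-tRNA synthetase gene yars1 (1.53, adjusted p = 0.000312) that effect lay above the effect at 4 h, when odc1 stood at 56 to 64.1 CPM in vehicle and 31 to 39.2 CPM in enoxolone. For apoa4a it lay below by 2.6 on the log2 scale (adjusted p = 0.00125) and for pnp4a by 2.09 (adjusted p = 6.54e-05). For insig1, hmgcra and fkbp5 a difference between durations did not pass (adjusted p = 0.57, 1 and 0.193). Without the library labelled vehicle 8 h, replicate 3, and with clutch as a block, it passed for 1 of these genes. The test therefore does not show that their effects were constant over time. Without clutch 1 the interaction test called 110 genes, without clutch 3 it called 281, and without clutch 2, where enoxolone at 24 h keeps 1 library, edgeR called 0 with 1541 at an unadjusted p under 0.05. With all libraries and without the one labelled vehicle 8 h, replicate 3, edgeR called 908 and 1136, and with all libraries DESeq2 called 1883 and the series covariate fit 1721.

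**Figure D2:**
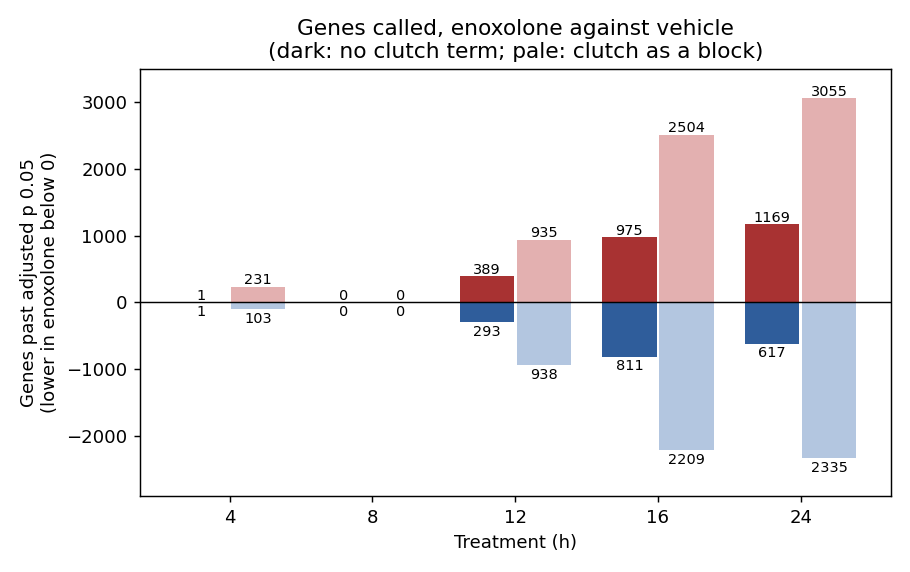
Number of genes past an adjusted p of 0.05 at each duration (hours), higher in enoxolone above the zero line and lower below it, for the test without a clutch term (dark bars) and with clutch as a block (pale bars). Without the block the calls number 2 at 4 h, 682 at 12 h and 1786 at both 16 and 24 h, the lower genes 811 at 16 h and 617 at 24 h, with 0 at 8 h, where the doubted library is a vehicle pool.

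Vehicle larvae at 24 and 4 h show the background change over the same span of development and clock time: 926 genes were higher at 24 h and 777 lower of 22371 in edgeR (2260 and 1918 with clutch as a block). Digestive enzyme genes had the largest rises. The elastase gene ela2l gave a log2 fold change of 7.67 ± 1.02 (edgeR adjusted p = 0.0234). The bile salt-activated lipase gene cel.1 went from 0.322 ± 0.32 CPM (n = 3) to 17.4 ± 11.4 CPM (n = 3), a log2 fold change of 5.6 ± 0.73. In the exocrine pancreas list 14 of 21 genes rose, 17 adjusted over the list alone (camera adjusted p 9.32e-11; adjusted p = 0.427 with an estimated correlation). In the intestine list 15 of 27 rose (24 with the block), 25 adjusted over the list alone (camera adjusted p 5.49e-13; adjusted p = 0.427 with an estimated correlation). Heat shock genes fell in 15 of 25 cases and 19 adjusted over the list alone (camera adjusted p 7.52e-14; adjusted p = 0.427 with an estimated correlation). The embryonic globin gene hbbe1.2 went from 367 ± 104 to 103 ± 23.9 CPM.

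Several genes that enoxolone raised also rose with time in vehicle alone. fkbp5 went from 3.83 ± 0.881 CPM at 4 h to 46.6 ± 31.6 CPM at 24 h (log2 fold change 3.62 ± 0.62, edgeR adjusted p = 0.0286), pck1 from 12.8 ± 0.974 to 53.3 ± 36.4 CPM, and hmgcra from 24.8 ± 6.45 to 60.7 ± 13.8 CPM. Of the cholesterol synthesis list 11 of 29 genes rose (17 rose and 1 fell with the block), and adjusted over the list alone 20 rose and 2 fell (camera adjusted p 1.19e-07; adjusted p = 0.427 with an estimated correlation). Without clutch 1, 2 or 3 the vehicle calls numbered 1005, 3 and 6.

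**Figure D3:**
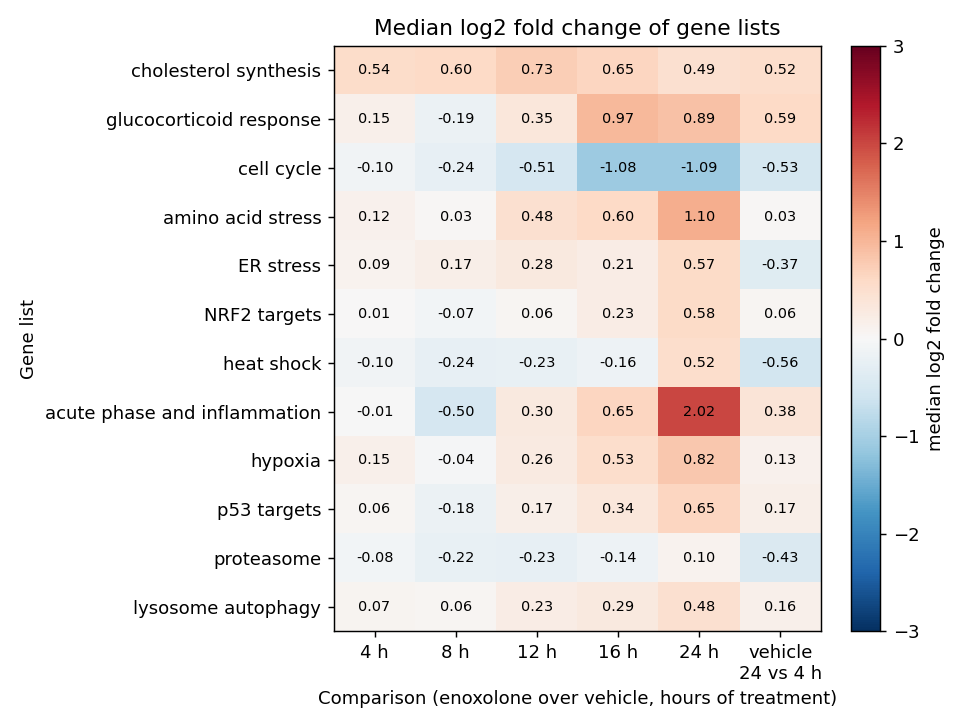
Median log2 fold change of 12 gene lists (rows) in the enoxolone comparisons at 4, 8, 12, 16 and 24 h and between vehicle 24 h and 4 h (columns); red is higher in enoxolone, or at 24 h in the last column, and blue lower. The cell cycle row reaches -1.09 at 24 h, and the acute phase row goes from -0.5 at 8 h, where the library labelled vehicle 8 h, replicate 3 is a vehicle pool, to 2.02 at 24 h.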

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

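The tests of the doubted library against enoxolone pools and against other vehicle pools, the fits without it, its clock values and shares, and the draws that permute durations were chosen only after the result was seen.

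The difference of the enoxolone effect between durations passed for 908 of 23857 genes in edgeR, and 30 of the 62 genes named in the enoxolone comparisons were among them. The naming rule drew on this same test and on the calls at each duration, so the 30 of 62 is a description and no test. Among these 30 the smallest adjusted p values of the interaction test belonged to timp2b (1.07e-05), pnp4a (6.54e-05), hsp70l, hsp70.2 and hsp70.3 (0.000237 each), yars1 (0.000312), odc1 (0.000337) and hsp70.1 (0.000416). Of the others, cxcl18b gave 0.00125, mmp9 0.0024, fosl1a 0.00384, isg15 0.00445 and adam8a, a leukocyte protease gene, 0.00981. Among stress genes xbp1 gave 0.00205, sesn2 0.00354, sqstm1 0.00603, ddit3 0.02, pmaip1 0.0203 and ctsba, a lysosomal protease gene, 0.0238. Metabolic and transport genes were apoa4a (0.00125), hsd11b2 (0.008), cyp26a1 (0.00879), arf4b (0.0133), tat (0.0184), aqp8b (0.0202), pfkfb3 (0.0254), apobb.2 (0.0258), igfbp1a (0.03) and gck (0.0344), and the proliferation gene mki67 gave 0.0103. When treatment labels were permuted within durations, 5 of 100 draws gave as many genes, with 2697 in the highest other draw, but such draws keep the effect at some durations and break it at others, so this count decides nothing. In another set of draws, the duration given to each enoxolone effect was permuted within clutches 2 and 3, with the vehicle levels kept. Only 1 of 100 draws, the real one, gave 908 genes, with 444 in the highest other. This argues against chance among the enoxolone libraries as the whole cause. The vehicle libraries were not permuted, so these draws cannot decide on chance among them.

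Between 24 h and 4 h the effect on 19 of 46 lists differed by camera with the preset correlation, 12 of them among the lists named in the enoxolone comparisons. For these 12 the adjusted p was 2.61e-18 for acute phase and inflammation, 3.04e-17 for cell cycle, 2.73e-15 for amino acid stress, 8.5e-15 for heat shock, 2.07e-13 for endoplasmic reticulum stress, 5.75e-12 for NRF2 targets and 8.52e-07 for lysosome and autophagy. It was 3.05e-05 for p53 targets and for hypoxia, 0.000689 for glucocorticoid response, 0.0023 for the proteasome and 0.007 for neutrophil and mast cell markers. With an estimated correlation the lowest adjusted p over all lists was 0.134.

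The library labelled vehicle 8 h, replicate 3, lies between the other vehicle 8 h pools and later enoxolone pools for pck1, at 147 CPM against 8.88 and 16.1 CPM in the former and 202 to 440 CPM in the latter; no biological explanation was tested. Its treatment score, from 232 genes that rose and 144 that fell at 12, 16 and 24 h, was 0.68 below the lowest of 5 enoxolone libraries of 16 and 24 h, which helped choose these genes, and from the 682 genes called at 12 h alone it was still 0.63 below (SD 0.05), which argues against a whole pool of that kind under a wrong label. It was 1.25 above the highest of the other 14 vehicle libraries, and from the genes of 12 h 0.86 above the highest of 11 vehicle libraries of other durations (SD 0.39), which argues against a vehicle pool of a later duration. Over 37 clock genes it lay 0.28 log2 from enoxolone 24 h, 0.47 from vehicle 24 h, 0.54 and 0.56 from enoxolone and vehicle 16 h, 1.9 from enoxolone 12 h and 1.64 from vehicle 8 h, and 19 of them gave a median share of 0.748 of the way from vehicle 8 h to enoxolone 24 h (0.904 and 0.648 with each far-end pool). A mixture of vehicle 8 h and enoxolone 24 h RNA would give similar shares in all sets of genes. That share was 0.548 for rising, 0.681 for falling and 0.402 for time-only genes, a largest difference of 0.28. By the bound set beforehand, 0.2 and the widest bootstrap interval of a median share (0.2), this counted against a mixture. That bound did not consider the choice of far-end pool, and the 2 far-end pools alone gave 0.11 and 0.32. The clock share lay 0.3 and 0.31 above the time-only share. The far-end pools themselves, each set against the other, gave 0.17 and -0.39. The outcome therefore hangs on the far-end pool, and a mixture cannot be told apart from other causes.

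The calls at 12, 16 and 24 h could come from the sequencing series, since the arms of clutch 2 lie in different inferred series while those of clutches 1 and 3 share one. Of 681 genes called at 12 h, 99.7% had the same sign at 16 h in clutches 1 and 3 alone, and of 1765 called at 24 h 97% did, which argues against the series as the whole cause. With the series as a covariate edgeR called 557, 1383 and 1975 genes at 12, 16 and 24 h. A part of single genes' changes from the series stays open.

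The splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.1. Only 1 of the 10, the real split, gave as many genes as itself at 12 h (682 genes, highest other 4), at 16 h (1786, highest other 1) and for vehicle 24 h against 4 h (1703, highest other 0 in edgeR). At 4 h 2 of 10 splits gave as many as the real 2 genes, the highest other also giving 2, or 1 among the splits that part every clutch. At 8 h the real split gave 0 in edgeR (928 at an unadjusted p under 0.05, 53 in DESeq2), all 10 gave as many, and the highest gave 459. That split set the library labelled vehicle 8 h, replicate 3, with enoxolone replicates 2 and 3, and it parts inferred series 1 from series 2; the same split gave 0, 1 and 0 genes at 4, 12 and 16 h. For the average effect only 1 of 100 draws, the real one, gave as many as 5441 genes, the smallest share these draws can give. The highest other gave 5181. It kept the real label in 7 libraries, 0 of them at 16 h and 1 at 24 h, so it came near to swapping the arms. The draws did not keep the clutch pairing. They argue against chance as the whole cause only within these limits.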

How the results depend on the processing

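Of the values for single genes under the alternatives, 1231 counted as unchanged in direction and side of the threshold. Another 84 kept direction but no longer passed, 28 newly passed and 9 reversed. A change of sign also counted as unchanged where neither fit passed and the new value was within the main fit's standard error. An example is apobb.1 at 4 h, at -0.22 in the main fit and 0.04 without replicate 1. For gene lists 589 kept direction and side of the threshold, 46 no longer passed and 3 reversed. Of those 46, 40 came from the estimated correlation. For genes tested for a difference between durations 126 kept their side of the threshold, 7 no longer passed and 1 newly passed, and direction was not compared. Scaling by DESeq2's size factors changed no call among the named genes and lists and moved no count by more than 1.5 times. The clutch block changed no other call than those given in the results. A GC correction was not run because no genome was given. Low depth limits genes near 1 CPM, which stands for 19 counts in the smallest library. The filter at 1 CPM ended the 2 calls at 4 h (adjusted p 0.0535 each), of genes far above that level. Where no cause is named, the cause was not tested.

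The values counted as reversed were all at 8 h. The log2 fold change of pck1 became 0.97 with the block, 0.94 with limma and a pseudocount of 0.1, 0.96 with the length trend removed and the block, and 1.94 without replicate 3. Without replicate 3 fkbp5 became 2.88 and the median of the acute phase and inflammation list 0.09. In the fits chosen after seeing the data, without the library labelled vehicle 8 h, replicate 3, pck1 became 2.15 and with the block 1.98, fkbp5 2.95 and 2.6, and the list 0.11 and 0.1. Over the left-out replicates the lowest values, without replicate 2, were -1.52 for fkbp5, -0.51 for pck1 and -0.66 for the list.

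Counts of called genes moved as follows. The DESeq2 test gave 115 at 4 h, 53 at 8 h, 1274 at 12 h, 2892 at 24 h, 1883 for the difference between durations and 3031 for vehicle. The clutch block gave 334, 1873, 4713 and 5390 at 4, 12, 16 and 24 h, 2596 for the difference and 4178 for vehicle. With the length trend removed as well the block gave 352, 1878, 4751 and 6193 at these durations and 4556 for vehicle, and without the block 4 h gave 7. With limma on log2(TPM + 1) the counts were 1, 153, 1017 and 1082 at 4, 12, 16 and 24 h, 558 for the difference and 530 for vehicle; with a pseudocount of 0.1 they were 149, 981 and 1020 at 12, 16 and 24 h and 473 for vehicle. With log2(TPM + 1) the median of all genes moved to -0.151 at 24 h (-0.196 with 0.1) and to 0.078 in vehicle (0.103 with 0.1). With log2(TPM + 1) 527 genes rose and 555 fell at 24 h, 413 and 604 at 16 h, 1538 and 2803 for the average and 439 and 91 in vehicle. All 29 libraries in the fit gave 8, 201, 420 and 4232 at 4, 8, 12 and 24 h and 3351 for vehicle, and with the block 15, 454, 1163, 3911 and 7035 at 4, 8, 12, 16 and 24 h and 6042 for vehicle. Without a filter 4 h gave 21, and with the filter at 1 CPM edgeR gave 0 of 19948 genes (1033 at an unadjusted p under 0.05), while the 115 of DESeq2 are of 28780 genes without that filter. The series covariate gave 1721 for the difference. Without the library labelled vehicle 8 h, replicate 3, 8 h gave 29 and with the block 688, the average 7138 and 9521, and the difference 1136 and 2655.

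Leaving out each replicate number gave 0 to 1 at 4 h (edgeR; 512 to 1361 at an unadjusted p under 0.05), 76 to 243 at 12 h, 200 to 650 at 16 h, 35 to 1596 at 24 h, 1927 to 5438 for the average, 0 to 281 for the difference (1541 unadjusted at the lowest) and 3 to 1005 for vehicle. These fits hold fewer libraries, and those with 1 enoxolone library at 24 h assume that it varies as the others do.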

Other observations

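The test of time advance and its bounds were set before its result was seen.

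In the circadian clock list 5 of 37 genes rose at 12 h and 8 adjusted over the list alone (camera adjusted p 6.5e-05; adjusted p = 0.292 with an estimated correlation). At 16 h 10 rose (21 rose and 3 fell with the block), and 16 rose and 1 fell adjusted over the list alone (camera adjusted p 1.72e-06; adjusted p = 0.241 with an estimated correlation). The clock repressor gene nr1d2a went from 33.4 ± 3.81 to 68 ± 2 CPM at 12 h and from 105 ± 40.3 to 263 ± 18.3 CPM at 16 h (n = 3 each), and the period gene per1a from 38.2 ± 7.49 to 77.5 ± 7.67 CPM at 16 h.

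At 16 h 5 of 28 genes of the epidermis list fell (4 rose and 14 fell with the block), and 3 rose and 9 fell adjusted over the list alone (camera adjusted p 0.0123; adjusted p = 0.468 with an estimated correlation); evpla, which encodes the cornified envelope protein envoplakin, fell from 94.4 ± 10.9 to 40.3 ± 3.32 CPM. In the pigment list 1 of 20 rose and 4 fell (2 and 7 with the block), and 2 rose and 5 fell adjusted over the list alone (camera adjusted p 0.0091; adjusted p = 0.558 with an estimated correlation), among them the pteridine synthesis gene gch2, from 102 ± 8.94 to 49.1 ± 17.3 CPM, and pnp4a, from 33.7 ± 3.07 to 7.66 ± 1.02 CPM. At 24 h, 12 of 30 lysosome and autophagy genes rose and 1 fell (21 and 1 with the block), or 18 and 1 adjusted over the list alone (camera adjusted p 1.51e-09; adjusted p = 0.448 with an estimated correlation), with ctsba at 140 ± 11 and 284 ± 43.8 CPM. Of 17 neutrophil and mast cell markers 4 rose (7 with the block) and 6 over the list alone (camera adjusted p 0.0136; adjusted p = 0.726 with an estimated correlation), with adam8a at 5.78 ± 0.281 and 15.3 ± 2.64 CPM.

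One hypothesis was that enoxolone may advance the time course that vehicle larvae go through from 4 to 24 h. Of the genes called in vehicle, 58.5% moved the same way under enoxolone at 12 h and 72.7% at 16 h. The bound set beforehand asked for more than 60% at both durations, so the share at 12 h counted against the hypothesis. But other splits of the same libraries reached 86.2% and 86%, in either direction. Shares of this size therefore arise between libraries, and the hypothesis cannot be told apart from that variation. Genes falling with time moved the same way in 75.2% and 82.2% of cases, genes rising with time in 44.4% and 64.8%. The exocrine pancreas and intestine lists, which rise with time, had medians of 0.34 and 0.1 at 16 h.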
